A study of Mus musculus with 8 samples.

How the data were processed

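Total RNA from CD31-positive kidney cells of adult mice was profiled on 1-colour Illumina BeadChips, with 1 array for each of 8 samples. Per the labels, RNA was isolated with a micro-scale column kit, its quality was checked on a Bioanalyser, and biotin-labelled cRNA was made with an Ambion amplification kit. The labels give the genotype and the sex of every sample, which makes 4 groups of 2: mutant females (numbers 1 and 3), mutant males (2 and 4), wildtype females (1 and 3) and wildtype males (2 and 4). The labels name 4 pairs of mice but do not state that each array holds RNA of a separate animal, so p-values measure only the spread between these samples, which may be technical.

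The deposited table of probe signals holds an intensity for 45281 probes on each array, on a linear scale, with no background subtraction or normalization visible in the values. A detection p-value stands beside each intensity, per the file headers. The scanner software and its version are not given in the sources used here. The authors' deposited processed values lie on a log2-like scale with a floor near 7.15 that compresses differences between dim probes, and their medians ran from 7.46 to 7.47. How the authors made them is not given in the sources used here, so their exact transformation stays unknown; they were used as an alternative. Each of these columns matched the signals of its own array (r across probes brighter than 200, after centring each probe, from 0.984 to 0.993) better than those of any other array (at most 0.525). There were 0 columns of values that could not be tied to a sample.

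Background was corrected with the normexp model fitted through the detection p-values, an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Probes with a detection p under 0.05 on at least 2 of the 8 arrays were tested, which left 23841 probes of 12474 named genes. Arrays have no read depth; the number of arrays limits the precision. The platform's annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378. Of the named probes, 34818 were updated through the Entrez identifier with the GRCm38.p6 gene table, which renamed 10, and 67 kept the older symbol. That table was used only for names and for the order of genes, and no coordinates are printed because the build behind the probes is not given in the sources used here. A gene was represented by its tested probe with the highest mean. Where another probe of a gene named by the rule below had the opposite sign in the genotype or sex effect it was named for, the results say so. Probes with the same sign but a smaller difference are not always given.

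A mean was fitted for each of the 4 groups, and the genotype effect (mutant minus wildtype, both sexes weighted equally), the genotype effect within each sex, their difference (the interaction) and the sex effect (male minus female) were tested as contrasts with limma (lmFit and eBayes, 4 residual and 3.07 prior degrees of freedom). P-values were two-sided and adjusted by the Benjamini-Hochberg method over probes, with a threshold of 0.05. Errors of differences are standard errors of that model. Where a probe was below its detection limit on all arrays of the dimmer side, the change is given as at least N-fold: the mean of the brighter side against the mean of, per array, the higher of the lowest signal among detected probes and the probe's own. The model was tested on simulated data over 23841 probes for the genotype effect. It recovered 78% of 50 probes changed by a log2 of 1 and 100% of those changed by 2, 3 or 4, with 14 false calls. The simulated noise was normal and independent between probes, and 50 probes were changed at each of the 4 sizes. On the real arrays genes vary together and fewer probes passed, so these shares may not hold there.

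Gene lists were fixed for endothelium in general (pan-endothelial) and for its glomerular, arterial, capillary and venous, and lymphatic kinds; for endothelial activation and adhesion, mesenchymal transition, collagens and matrix, VEGF signalling, TGF-beta and BMP signalling, interferon response, antigen presentation, proliferation, immediate early and dissociation stress, hypoxia and glycolysis, mitochondrial oxidative phosphorylation and tubule injury; for other cells (podocyte, proximal tubule, loop and distal tubule, collecting duct, mural and mesangial, fibroblast, macrophage and dendritic, T and NK, B and plasma, neutrophil, platelet, erythroid); and for sex-linked genes. The 30 lists share some members; genes with no tested probe were not analysed here, among them Col1a1, Col3a1 and Kdr. Lists were tested with camera in limma, which asks whether the genes of a list moved relative to all others, with a preset correlation of 0.01 between genes and adjustment over the 30 lists of a contrast. An estimated correlation and fry, which asks whether a list moved on balance one way, were alternatives. In simulated data, 15 independent genes shifted by 0.5 were called in 100% of 200 runs with the preset and 99.5% with an estimated correlation. A list of 15 unchanged genes that shared a common factor (correlation 0.4) was called in 42% and 4% of runs, so a camera call with the preset value can come from genes that vary together between arrays. Shifted genes that vary together were not simulated, and the estimated correlation was 0.76 in the pan-endothelial list. How often the test with an estimated correlation misses a real shift in such a list is therefore unknown.

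The design, the tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes Crim1, the 10 genes per direction past the threshold with the same direction in both sexes (places left open were filled with the smallest unadjusted p, and the text says that these did not pass), 2 members of each list with the smallest p and every member past the threshold; for the sex effect, the sex-linked genes and the 5 highest and 5 lowest differences; and for the other contrasts, the 3 smallest p in each direction. Other genes named from lists are those that passed when adjusted over the list alone, and were chosen after their values were seen.

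Alternatives were other background corrections (normexp with an offset of 50, or none), median scaling or cyclic loess in place of quantile normalization, the authors' values, no filter or a strict filter (detection p under 0.01 on all 8 arrays), sex as an additive term or no sex term, the sample number as a fixed or random block, array weights, probes averaged per gene, and leaving out each array in turn. The mean of the pan-endothelial genes as a covariate was added after the data had been seen, as were the tests of lists without background correction, with median scaling and with cyclic loess. Because the study describes its mice as 4 pairs and each mutant shares its number with a wildtype sample of the same sex, it was checked whether same-numbered samples deviated together from their group means. With groups of 2, both pairs of a sex give the same correlation, and swapped numbers would only change its sign. It was 0.100 in females and 0.270 in males, above 0.1 in every pair (narrowly so in females), so the numbers were taken to pair the samples. Positive values in both sexes can arise by chance, so this is weak support for pairing. The fixed block is called the replicate block below, and its value is given beside a result where it changed the call.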

Results

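Gene expression was profiled in endothelial cells of adult mouse kidneys, collected by magnetic sorting for the surface protein CD31 (encoded by Pecam1). Mutants were homozygous for KST264, a gene-trap allele of Crim1, which encodes a transmembrane protein with cysteine-rich repeats that binds bone morphogenetic proteins; wildtype mice served as controls. The mice had a mixed C57B6/CD1 background. There were 4 mutant and 4 wildtype arrays, each with 2 females and 2 males. The median raw signal of an array ran from 83.2 (mutant male 2) to 98.5 (wildtype male 2 and mutant female 3), and 45.1% to 48.7% of the probes were detected.

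The sexes separated on the first principal component, which held 35.2% of the variance. On the second component (18.4%), mutant male 2 stood at 53.7 and the other arrays between -39.8 and 3.44. Transcripts of tubule epithelium gave bright signals on every array despite the CD31 sort. The median gene of the proximal tubule list lay at percentile 98.4 to 99.3 of all probes on an array and that of the loop and distal tubule list at 98.8 to 99.3; that of the pan-endothelial list lay at 90.1 to 96.9. Umod, the main protein secreted by the thick ascending limb, reached percentile 99.7 or higher on each array. The endothelial genes Emcn (98.6 to 99.7) and Egfl7 (98.2 to 99.6) were as bright as many tubule genes, and Pecam1 lay between 90.0 and 96.6. Signals of different probes depend on their affinity as well, so these percentiles do not measure shares of tubule and endothelial RNA.

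The level of Crim1 itself was examined as a check of the genotype labels. Its transcript was 5.02-fold lower in mutants than in wildtype arrays by probe ILMN_2910295, with a log2 difference of -2.33 (SE 0.17, adjusted p = 0.0365). Mean log2 intensity was 5.29 ± 0.607 (SD, n = 4) in mutants and 7.62 ± 0.463 (SD, n = 4) in wildtype arrays, and no mutant array (4.67 to 5.81) overlapped the wildtype range (6.96 to 7.98). A further probe, ILMN_2525274, gave -2.29 (SE 0.21, adjusted p = 0.0365), a 4.87-fold lower level. Its mutant signal was largely background, so the size of this fold is uncertain. By the first probe Crim1 was 4.36-fold lower in females, and the signal of both mutant males was not well above background. The signal was detected on 4 of 4 wildtype arrays for both probes, and on 2 and 1 of 4 mutant arrays. The remaining probe, ILMN_1256087, was not well above background on any array and was not tested. With the replicate block the difference stayed at -2.33 (SE 0.18) but its adjusted p was 0.147. With the sample number as a random block it was -2.33 (SE 0.16, adjusted p = 0.0285). Leaving out single arrays gave differences of -2.50 to -2.15, and the call held only without wildtype male 4 (adjusted p = 0.0225; 0.0547 without wildtype male 2 to 0.217 without wildtype female 3). Where the probes lie relative to the trap insertion is not given in the sources used here, so transcript upstream of it may not be measured.

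**Figure D1:**
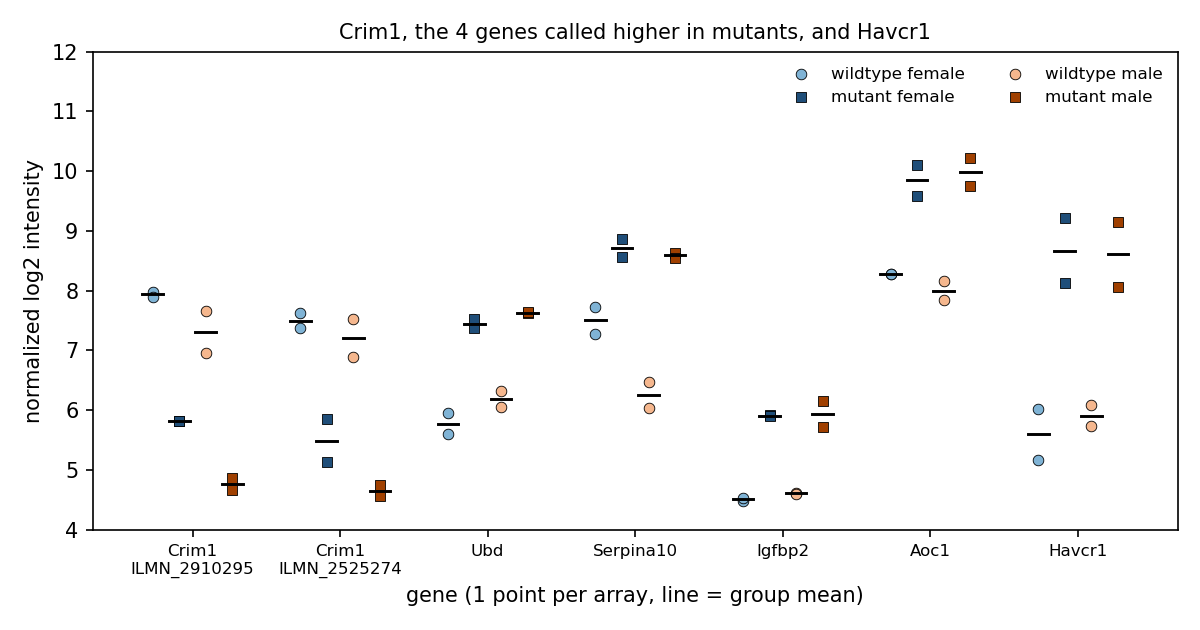
Normalized log2 intensity (vertical axis) of 2 Crim1 probes, the 4 genes called higher in mutants and Havcr1; each point is 1 array, colours and shapes mark genotype and sex, and lines are means of 2 arrays. Mutant arrays lie below all wildtype arrays for Crim1 (-2.33 for ILMN_2910295) and above them for Ubd (1.56) and Igfbp2 (1.37), while Havcr1 (2.88) did not pass the threshold.

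The main comparison asked which genes differ between mutant and wildtype endothelial fractions over both sexes. Besides Crim1, 4 genes passed, all higher in mutants. Aoc1, which encodes the histamine-degrading diamine oxidase, was 3.42-fold higher (log2 1.77, SE 0.17, adjusted p = 0.0428). Serpina10, an inhibitor of coagulation proteases, was 3.41-fold higher (1.77, SE 0.16, adjusted p = 0.0365), and Ubd, a ubiquitin-like modifier induced by cytokines, was 2.95-fold higher (1.56, SE 0.13, adjusted p = 0.0365). Igfbp2, which binds insulin-like growth factors, was not well above background on any of the 4 wildtype arrays and at least 1.61-fold higher in mutants (1.37, SE 0.13, adjusted p = 0.0365); its other probe gave 0.73 (adjusted p = 0.218). Each of these genes had the same direction in females and males, and Serpina10 differed by 1.21 in females and 2.33 in males. With the replicate block none of the 4 passed (adjusted p = 0.220 for Aoc1, 0.458 for Serpina10, 0.147 for Ubd and 0.166 for Igfbp2). All 4 passed with the sample number as a random block.

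In all, 9 of 23841 probes passed (6 higher, 3 lower in mutants), and 2090 had an unadjusted p under 0.05. Chance gives 1192 for independent probes, but in the fit with sex as an additive term another split of the arrays, with 3 mutants and 3 females on the same side, gave 2076 and the real one 1853, so chance is not excluded for this excess. Among splits balanced for sex the highest other gave 1811, close below the real one. The other called probes were 1 with no gene name (ILMN_2759484, 1.62), 1 of Gabrp, a GABA receptor subunit (1.52; its brighter probe gave 1.63, adjusted p = 0.330), and 1 of the transcription factor Zfp24 (-1.36). The Zfp24 probe differed by -0.12 in females and -2.59 in males, and the gene's brighter probe by -0.15 (adjusted p = 0.790). The count fell to 0 with the sample number as a fixed block (the replicate block) and stayed at 9 with it as a random block. When any 1 of the 8 arrays was left out, none of the 9 calls held except that of Crim1 without wildtype male 4. It was 0 in the authors' processed values, 1 without a filter, 4 with the strict filter and 3 without a sex term.

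Among the genes that came closest without passing, Havcr1, the kidney injury molecule of damaged proximal tubules, showed the widest difference: 7.37-fold higher in mutants (log2 2.88, SE 0.35, adjusted p = 0.166). The others on the higher side were Atp12a, a proton and potassium pump (1.49), the receptor Pdgfra (1.27), Loxl1, which cross-links elastin and collagen (1.25), Plet1 (0.89) and the proteoglycan Dcn (0.88). A dimmer Dcn probe went the other way (-0.86, adjusted p = 0.356). On the lower side were Spink6 (-1.31), Erich5 (-1.14), Zxda (-1.03), Gm4951 (-1.01), Cntnap2 (-0.97), the cytotoxic granule protein Prf1 (-0.97), Rhbdl2 (-0.88), the interferon-gamma receptor chain Ifngr2 (-0.72), Azin2 (-0.71) and the immediate early gene Ier2 (-0.67). Azin2 and Cntnap2 were not well above background on any mutant array (at least 1.20-fold and at least 1.39-fold lower). The adjusted p of all these genes ran from 0.166 to 0.330. Dimmer probes of Prf1, Azin2, Ifngr2 and Gm4951 gave values above 0 (0.04 to 0.24), and those of Cntnap2 gave -0.24 and 0.09. The dimmer Spink6 probe gave -0.31.

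Of the 30 gene lists, 13 passed in the genotype contrast, 6 higher and 7 lower in mutants. None passed with an estimated correlation (smallest adjusted p = 0.396 with an estimated correlation) or with fry (smallest adjusted p = 0.121). The adjustment gave 0.396 to several lists whose unadjusted camera p with an estimated correlation differed, such as tubule injury (0.0146) and pan-endothelial genes (0.145). No member of any list passed over all genes. The highest shift was that of tubule injury markers, whose 10 measured genes all lay above 0 with a median of 0.75 (adjusted p = 4.58e-10, and adjusted p = 0.396 with an estimated correlation). Adjusted over the list alone, 7 of them were higher: Havcr1, the iron-binding protein Lcn2 (1.92, SE 0.44), Krt19 (at least 2.07-fold), Timp1 (1.00, SE 0.22), Cp (0.82, SE 0.19), Krt18 (0.68, SE 0.16) and Krt20 (0.65, SE 0.20). Among markers of intact tubule, the collecting duct list was higher by a lesser 0.19 (adjusted p = 0.0109, and adjusted p = 0.659 with an estimated correlation), and the others did not pass: the median was 0.00 for the proximal tubule (adjusted p = 0.758) and -0.01 for the loop and distal tubule (adjusted p = 0.816). Their members with the smallest p were the transporters Slc13a3 (0.40, with 1 dimmer probe at -0.03) and Slc12a3 (-0.30), the gluconeogenic enzyme Pck1 (0.39) and Pvalb (-0.87).

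Fibroblast genes were higher in mutants by a median of 0.44 (5 of 7 above 0, adjusted p = 0.00122, and adjusted p = 0.396 with an estimated correlation). Adjusted over the list alone, 4 were higher against 0 over all genes: Fbln1 (1.33, SE 0.21), Pdgfra (1.27, SE 0.17), Dcn (0.88, SE 0.12) and Serpinf1 (0.44, SE 0.12). Collagens and matrix genes shifted by 0.21 (17 of 26 above 0, adjusted p = 0.00265, and adjusted p = 0.659 with an estimated correlation), with Loxl1, Timp1, Dcn, Mmp2 (0.98) and Col6a1 (0.95) higher over the list alone. Without mutant male 4 the matrix shift was 0.08 (adjusted p = 0.620), and without wildtype male 4 it was 0.13. The hypoxia and glycolysis list shifted by 0.17 (adjusted p = 0.00768, and adjusted p = 0.396 with an estimated correlation), with P4ha1 (0.59; its other probe 0.12) and Adm (0.55) higher over the list alone; without mutant male 4 it gave 0.13 (adjusted p = 0.0603) and without wildtype male 2 it gave 0.15 (adjusted p = 0.103). Macrophage and dendritic cell genes shifted by 0.33 and collecting duct genes by 0.19 (both adjusted p = 0.0109, and adjusted p = 0.659 with an estimated correlation), with 0 members of either past the threshold over the list alone; Mrc1 stood at 0.57 and C1qa at 0.51, the water channel Aqp2 at 0.53 and Atp6v1g3 at 0.41. The macrophage call was lost without mutant female 1 (0.17), mutant male 2 (0.13), wildtype female 3 (0.23) or wildtype male 4 (0.15), and the collecting duct call without mutant female 1 (0.16), mutant male 4 (0.05), wildtype female 3 (0.14) or wildtype male 4 (0.14); without mutant male 2 the collecting duct shift was 0.30.

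Endothelial genes were lower in mutants over both sexes, mainly through the males (pan-endothelial median -0.96, against -0.18 in females). The pan-endothelial list had a median of -0.57, with 18 of 19 genes below 0 (adjusted p = 3.31e-09, and adjusted p = 0.396 with an estimated correlation). The receptor Tie1 was lower over the list alone (-0.87, SE 0.16), and Esam, an endothelial adhesion molecule, stood at -0.60 (SE 0.18). Arterial genes had a median of -0.45 (12 of 15 below 0, adjusted p = 8.79e-05; Hey1 -0.52, Sox17 -0.48), capillary and venous genes -0.43 (8 of 11 below 0, adjusted p = 0.00265) and glomerular genes -0.33 (6 of 7 below 0, adjusted p = 0.00768), each with adjusted p = 0.396 with an estimated correlation. Over the list alone Ehd3 (-1.15, SE 0.29) and Hecw2 (-0.88, SE 0.22) were lower among glomerular genes, and Npr3 (-0.99, SE 0.25) and Gpihbp1, the capillary anchor of lipoprotein lipase (-0.70, SE 0.17), among capillary and venous genes. Single arrays moved these medians without ending a call. Without mutant male 2 they were -0.32 for pan-endothelial, -0.29 for arterial, -0.21 for glomerular and -0.09 for capillary and venous genes. The capillary and venous median was -0.74 without mutant male 4 and -0.23 without wildtype male 4, which also brought the glomerular one to -0.21. Lymphatic genes stood at 0.00 (adjusted p = 0.843; Pdpn 0.49, Mmrn1 -0.68).

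Genes of TGF-beta and BMP signalling, the pathway of the proteins that Crim1 binds, had a median of -0.30 (18 of 23 below 0, adjusted p = 9.60e-05, and adjusted p = 0.396 with an estimated correlation). No member passed over the list alone; Ltbp1, which binds latent TGF-beta, stood at -1.05 (SE 0.24; its dimmer probe 0.18) and the BMP receptor Acvrl1 at -0.67 (SE 0.20). Interferon response genes had a median of -0.37 (12 of 14 below 0, adjusted p = 4.26e-05; Stat2 -0.68, Usp18 -0.57) and antigen presentation genes -0.19 (9 of 15 below 0, adjusted p = 0.0249; H2-D1 -0.40, Psmb8 -0.34), both with adjusted p = 0.396 with an estimated correlation. The antigen presentation call was lost with the replicate block (adjusted p = 0.153) and without mutant female 3 (-0.19, adjusted p = 0.157), mutant male 4 (-0.16, adjusted p = 0.277), wildtype female 3 (-0.17, adjusted p = 0.117) or wildtype male 2 (-0.23, adjusted p = 0.0713).

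The remaining lists did not pass. VEGF signalling had a median of 0.00 (adjusted p = 0.158), with Mef2c lower over the list alone (-0.69) and Vegfd at -0.48. Immediate early and dissociation stress genes had a median of 0.01 (mean -0.09, adjusted p = 0.241), with Ier2 lower over the list alone and Hspa1a at -0.43. Medians were 0.22 for podocyte (adjusted p = 0.107, and 0.0136 with the replicate block; Tcf21 0.74, Npnt 0.35), -0.06 for mural and mesangial (adjusted p = 0.170; Abcc9 -0.60, Mcam -0.46) and 0.19 for endothelial activation and adhesion genes (adjusted p = 0.843; Irf1 -0.35, and Ccl2 at least 1.12-fold higher). Mesenchymal transition genes had a median of 0.06 (mean -0.04, adjusted p = 0.758; Tgfb1 -0.50, and Fn1 at least 1.09-fold higher), and proliferation genes one of 0.07 (adjusted p = 0.758; Rrm2 0.35, Mcm6 -0.28). Oxidative phosphorylation genes had a median of 0.00 (adjusted p = 0.843), with Uqcrc2 at 0.11 and Atp5b at -0.06, the latter at 0.03 with median scaling.

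Blood cell lists did not pass either, with adjusted p between 0.796 and 0.843. Their medians were 0.06 for T and NK cells (Ccl5 0.98, Il2rb -0.18), -0.07 for B and plasma cells (Cd79b -0.18, Cd22 -0.09), 0.02 for platelets (mean -0.01; Clec1b 0.24, Ppbp -0.45) and -0.53 for erythroid genes (Slc4a1 0.23, Hba-a1 -0.77). Neutrophil genes had a median of -0.03 (mean 0.10), with Lcn2 higher over the list alone and Retnlg at -0.59. Sex-linked genes had a median of 0.04 between genotypes (adjusted p = 0.862).

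With the mean of the pan-endothelial genes as a covariate, chosen after the data were seen, 7 of the 13 list calls between genotypes were lost. For the pan-endothelial list itself (-0.07, adjusted p = 0.438) this follows from the choice of covariate. The others were glomerular (-0.11, adjusted p = 0.201), arterial (-0.08), TGF-beta and BMP (-0.05, both adjusted p = 0.228), capillary and venous (-0.03, adjusted p = 0.627) and interferon genes (-0.07, adjusted p = 0.704), and macrophage and dendritic cell genes, whose sign changed (-0.09, adjusted p = 0.392). These calls are not separable here from the level of the endothelial list. Injury (0.95), fibroblast (0.57), matrix (0.37), collecting duct (0.36), hypoxia (0.21) and antigen presentation genes (-0.22) kept theirs. In males the pan-endothelial (-0.06), arterial (-0.06), capillary and venous (-0.01), endothelial activation (-0.19), TGF-beta and BMP (-0.07) and interferon (-0.19) calls were lost, with adjusted p from 0.135 to 0.809, and the glomerular one held (-0.48, adjusted p = 0.0371). In females only the mural call was lost (-0.25, adjusted p = 0.0588). In the interaction the pan-endothelial (-0.04), arterial (0.01), matrix (0.08), interferon (0.02), proximal tubule (0.22) and fibroblast (-0.64) calls were lost, with adjusted p from 0.0958 to 0.934.

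**Figure D2:**
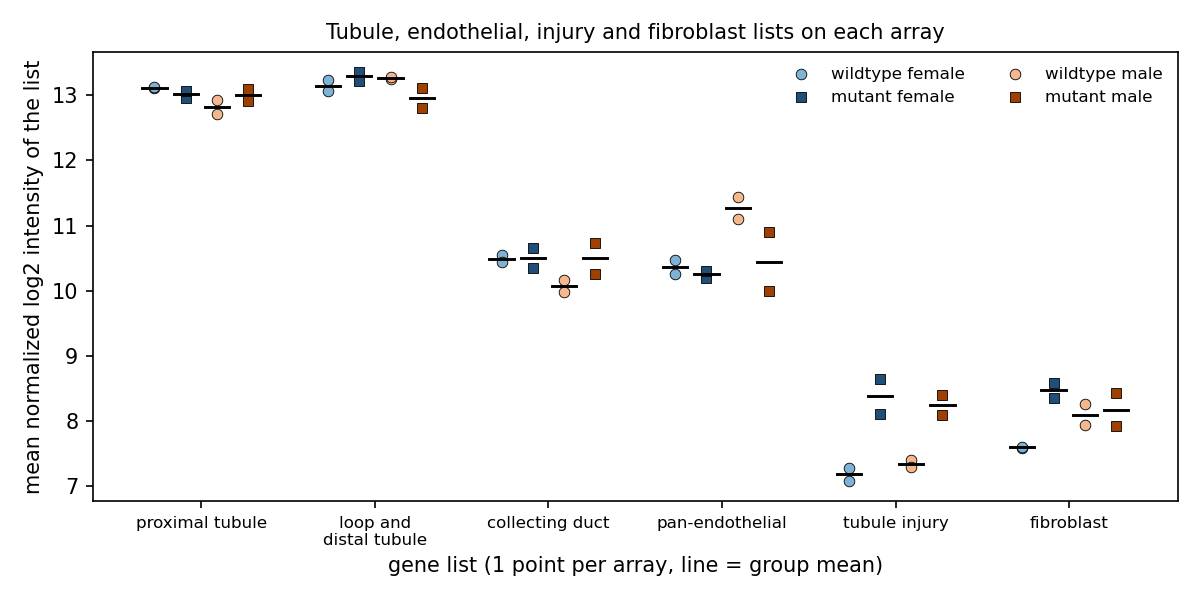
Mean normalized log2 intensity (vertical axis) of 6 gene lists on each array; colours and shapes mark genotype and sex, and lines are means of 2 arrays. The tubule injury list lies higher on all 4 mutant arrays (8.09 to 8.65) than on the wildtype arrays (7.07 to 7.40), and the pan-endothelial list is highest in wildtype males (11.10 and 11.45).

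Within females, injury and fibroblast genes had the widest medians of the called lists. The injury list was higher by a median of 1.05 (10 of 10 above 0, adjusted p = 1.75e-10), with 6 genes higher over the list alone, the widest being Havcr1 (3.07, SE 0.49) and Lcn2 (2.06, SE 0.62). Fibroblast genes were higher by 0.78 (adjusted p = 2.70e-08), with Fbln1 (1.91), Dcn (1.63), Pdgfra (1.37) and Serpinf1 (0.78) higher over the list alone. Collagens and matrix genes shifted by 0.44 (adjusted p = 1.64e-07) and endothelial activation and adhesion genes by 0.51 (adjusted p = 4.02e-05, with Csf3 higher over the list alone). The other called lists were macrophage and dendritic (0.43, with the mannose receptor Mrc1 higher over the list alone at 1.12), neutrophil (0.54), podocyte (0.34), hypoxia and glycolysis (0.20), platelet (0.20, with Pf4 and Clec1b higher over the list alone) and, on the lower side, mural and mesangial (-0.25, adjusted p = 0.0154). All 10 calls were lost with an estimated correlation (smallest adjusted p = 0.329 with an estimated correlation). The pan-endothelial median was -0.18 (adjusted p = 0.125) and that of TGF-beta and BMP signalling -0.19 (adjusted p = 0.0575), and both passed with the replicate block (adjusted p = 0.0297 and 0.0316).

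No probe passed in females with limma (2 against 2, 1013 with an unadjusted p under 0.05, smallest adjusted p = 0.237). The smallest p values belonged to Dcn (3.09-fold higher, SE of the log2 difference 0.17), Ubd (log2 1.67, SE 0.18) and Igfbp2 (at least 1.60-fold higher), and on the lower side to Crim1 (-2.12, SE 0.24), Tnfrsf19 (at least 2.02-fold lower) and Wdr25 (-1.07, SE 0.17). The smaller calls rested on single arrays: without mutant female 1 the podocyte shift was 0.00, the neutrophil shift 0.23, the platelet shift 0.14 and the hypoxia shift 0.15. Without wildtype female 1 the podocyte (0.38), neutrophil (0.26), platelet (0.01) and hypoxia (0.30) calls were lost too, without wildtype female 3 the podocyte (0.32) and mural (-0.12) calls, and without mutant female 3 the mural median was 0.02. Other calls held with a moved median. Without mutant female 1 it was 0.09 for macrophage and dendritic cell, 0.25 for endothelial activation and -0.48 for mural genes. Without wildtype female 3 it was 0.27 for matrix, 0.29 for endothelial activation, 1.12 for neutrophil and 0.37 for platelet genes, and without mutant female 3 it was 0.71 for podocyte and 0.45 for platelet genes.

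Within males, pan-endothelial, capillary and venous, and glomerular genes had the widest medians of the called lists. Erythroid (-1.37) and neutrophil genes (-1.08) had wider ones that did not pass (adjusted p = 0.938 and 0.179). The pan-endothelial list had a median of -0.96 (18 of 19 below 0, adjusted p = 8.55e-10), and 11 of its genes were lower over the list alone, among them Tie1 (-1.35, SE 0.22), Sox18 (-1.30, SE 0.42), Pecam1 (-1.16, SE 0.31) and Cdh5 (-1.11, SE 0.30). Capillary and venous genes had a median of -0.94 (2 lower over the list alone, Gpihbp1 -1.54), glomerular genes -0.87 (4 lower, Ehd3 -1.80) and arterial genes -0.65 (3 lower, Hey1 -1.01). TGF-beta and BMP signalling stood at -0.35, with 6 genes lower, among them Ltbp1 (-1.70), and 2 higher, Bmp4 (0.71) and Bmpr1a (0.56), over the list alone. Interferon response stood at -0.58 (5 lower), endothelial activation and adhesion at -0.19 (1 lower, Irf1 -0.75) and antigen presentation at -0.23 (3 lower; its mean was 0.12, opposite in sign). Tubule injury genes were higher by 0.85 (8 of 10 above 0, adjusted p = 0.000115, 7 over the list alone) and collecting duct genes by 0.37 (15 of 15 above 0, adjusted p = 0.000708). All 10 calls were lost with an estimated correlation (adjusted p = 0.345 with an estimated correlation, and 0.419 for the collecting duct). VEGF signalling (-0.13, adjusted p = 0.105), proximal tubule (0.09, adjusted p = 0.0534) and B and plasma cell genes (-0.35, adjusted p = 0.294) did not pass, but did with the replicate block (adjusted p = 0.0304, 0.0426 and 0.0291).

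Males had 1 called probe, the Zfp24 probe named above (adjusted p = 0.0101), and 2677 probes with an unadjusted p under 0.05. Serpina10 (5.05-fold higher, SE of the log2 difference 0.23, adjusted p = 0.127), Aoc1 (1.98) and Ubd (1.44) came closest on the higher side, and Crim1 (at least 4.12-fold lower), Spink6 (at least 3.32-fold lower) and Erich5 (-1.64) on the lower. The count was 0 with the replicate block and 1 with the random block. When single arrays were left out, the call of the Zfp24 probe held only without mutant male 2. The medians hung on single arrays. Without mutant male 2 they were -0.51 for pan-endothelial (adjusted p = 0.000175), -0.18 for capillary and venous (adjusted p = 0.0438), -0.39 for arterial, -0.37 for interferon, -0.19 for TGF-beta and BMP, -0.43 for antigen presentation and 0.62 for collecting duct genes. Without mutant male 4 they were -1.43 for capillary and venous, -0.98 for interferon, -0.65 for TGF-beta and BMP and -0.30 for endothelial activation genes. Without wildtype male 4 they were -0.56 for capillary and venous, -0.43 for arterial, -0.21 for TGF-beta and BMP and -0.29 for endothelial activation genes, and without wildtype male 2 -0.54 for TGF-beta and BMP and -0.31 for endothelial activation genes. Without mutant male 4 the collecting duct median was 0.15 (adjusted p = 0.223) and the antigen presentation call was lost (-0.20, adjusted p = 0.285), as it was without wildtype male 2 (-0.27, adjusted p = 0.0703) and with the replicate block (adjusted p = 0.0742).

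**Figure D3:**
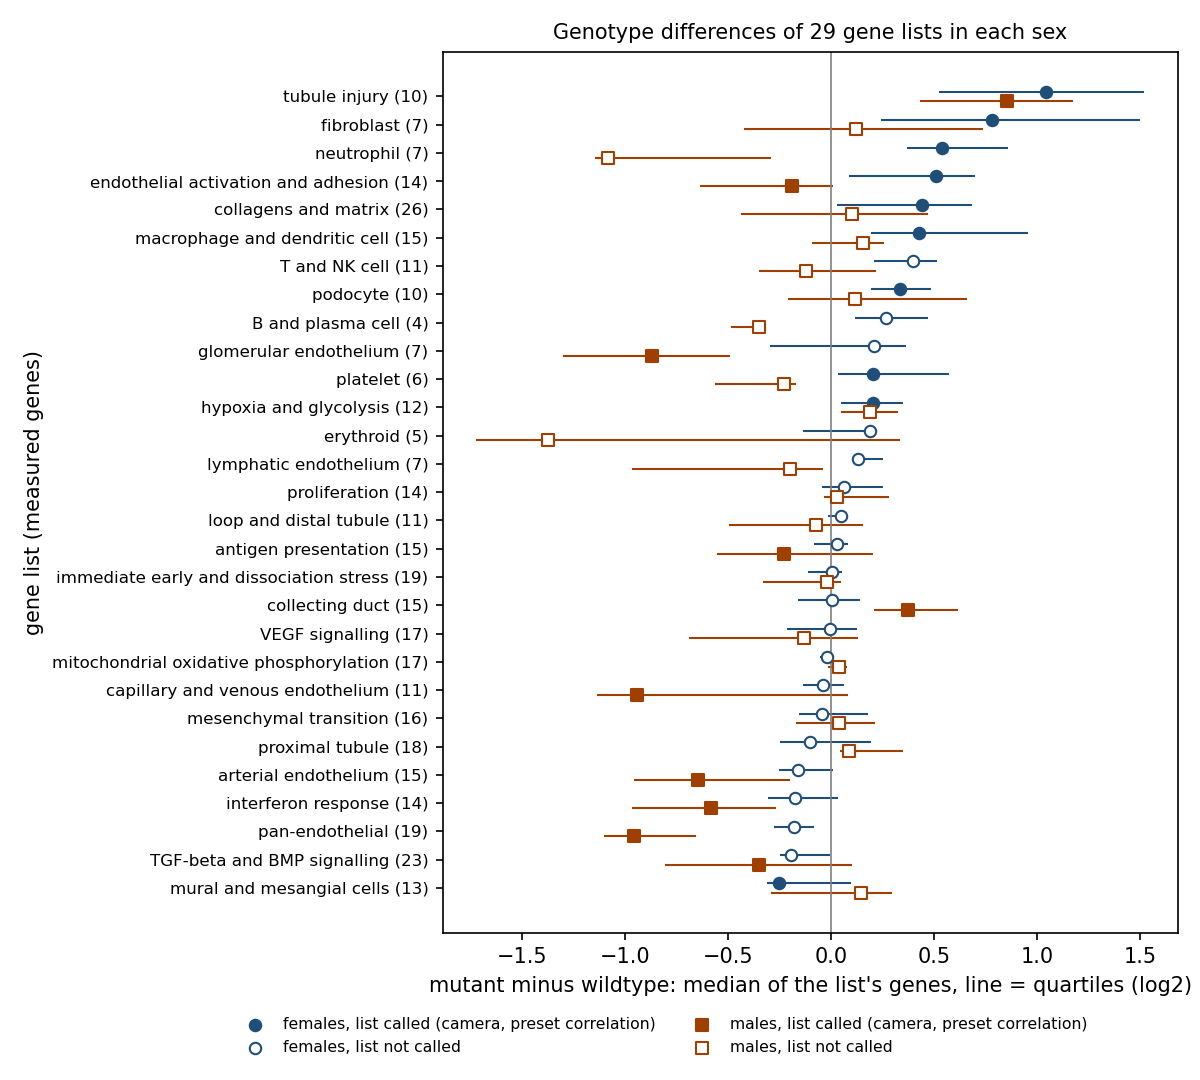
Median mutant minus wildtype difference (horizontal axis, log2) of each gene list in females (circles) and males (squares), with lines from the lower to the upper quartile of its genes and the number of measured genes in brackets; filled symbols passed camera with the preset correlation. Tubule injury lies to the right in both sexes (1.05 and 0.85), and the pan-endothelial list lies at -0.18 in females and -0.96 in males.

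Whether the genotype difference itself depended on sex was tested with the interaction. No probe passed with limma (1659 with an unadjusted p under 0.05, smallest adjusted p = 0.152). The named genes with the smallest p all had adjusted p = 0.591: Cfi, complement factor I (-0.71 in females, 1.38 in males), Mtmr4 (-0.57 and 0.78), Creld2 (-0.35 and 1.00), the chemokine Ccl6 (0.90 and -1.04), the platelet factor Pf4 (0.90 and -0.66) and Bambi-ps1 (0.58 and -0.85). Across the tested probes, which are not independent replicates, the female and male differences had a Pearson r of 0.0128, and 50.8% had the same sign. Among the 100 genes with the smallest genotype p, a ranking that favours a shared direction, 97 did.

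At the level of lists, 12 differed between the sexes. The male difference lay below the female one for pan-endothelial genes by a median of -0.86 (adjusted p = 1.03e-05), and for glomerular (-1.07), fibroblast (-0.90), neutrophil (-0.98), endothelial activation (-0.68), platelet (-0.59), macrophage and dendritic (-0.52), interferon (-0.44), arterial (-0.40) and matrix genes (-0.31). It lay above for collecting duct (0.47) and proximal tubule genes (0.23). None of these calls held with an estimated correlation (smallest adjusted p = 0.355 with an estimated correlation). Tubule injury genes did not differ detectably between the sexes (-0.27, unadjusted p = 0.383). With the replicate block the lists of capillary and venous (-0.62, adjusted p = 0.00443 against 0.0522 without it), TGF-beta and BMP (-0.27, adjusted p = 0.0399 against 0.104) and B and plasma cell genes (-0.57, adjusted p = 0.00443 against 0.175) passed too. Without mutant male 2 the arterial (-0.28), matrix (-0.09), interferon (-0.24) and proximal tubule (0.21) calls were lost. Without mutant male 4 those of the collecting duct (0.14), macrophage (-0.31) and neutrophil (-0.36) lists were lost. Leaving out wildtype male 2 ended the macrophage (-0.21) and neutrophil (-1.02) calls, wildtype male 4 the arterial (-0.18), interferon (-0.22) and proximal tubule (0.21) calls, mutant female 3 the collecting duct (0.18) and interferon (-0.16) calls, and wildtype female 1 the arterial call (-0.33). Calls that held moved too: without mutant male 2 the pan-endothelial value was -0.33, the glomerular one -0.68 and the neutrophil one -1.64. Without mutant male 4 the values were -1.32 for pan-endothelial, -1.43 for fibroblast, -0.70 for matrix, -0.84 for interferon and -0.35 for platelet genes, and without wildtype male 4 -0.56 for both pan-endothelial and fibroblast genes. Without mutant female 1 they were 0.74 for collecting duct, -0.74 for interferon and -0.36 for platelet genes, and without mutant female 3 -0.65 for glomerular genes. Without wildtype female 1 they were -0.30 for platelet and 0.37 for proximal tubule genes, and without wildtype male 2 0.43 for proximal tubule genes.

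**Figure D4:**
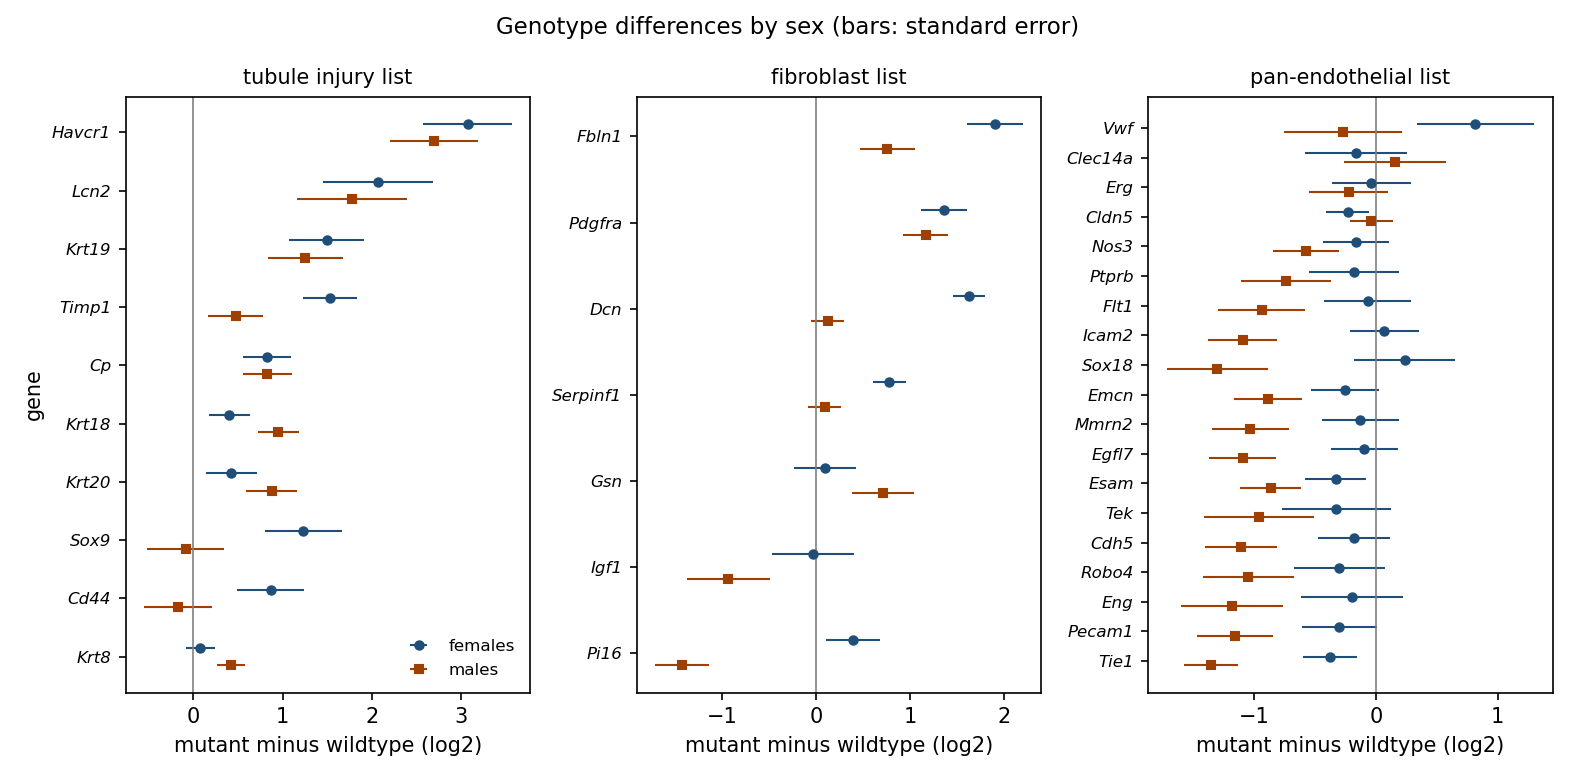
Mutant minus wildtype difference (horizontal axis, log2) of each measured gene of the tubule injury, fibroblast and pan-endothelial lists in females (circles) and males (squares), with bars of 1 standard error. Havcr1 differed by 3.07 in females and 2.69 in males, Dcn by 1.63 and 0.12, and Pecam1 was at -1.16 in males.

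The sex of the samples, given by the labels, had the widest effect. Xist, the RNA that silences an X chromosome, was at least 50.1-fold higher in females, and the Y-linked genes Eif2s3y and Kdm5d were at least 47.4-fold and at least 4.94-fold higher in males; Uty was 2.64-fold higher (adjusted p = 0.0232). The X-linked Eif2s3x (-0.77) and Kdm6a (-0.73) were lower in males, while Ddx3x (-0.14) and Kdm5c (0.02) did not pass. Each of the 6 genes that passed parted all female from all male arrays. A dimmer Eif2s3y probe gave 0.34 (adjusted p = 0.256) and 1 of the dimmer Kdm6a probes -0.34 (adjusted p = 0.495), and those of Kdm5c gave -0.14 and 0.18. The calls of Uty, Kdm6a and Eif2s3x were each lost without any of 6 arrays (Uty and Kdm6a without any female or either wildtype male, Eif2s3x without any female, wildtype male 2 or mutant male 4), with adjusted p up to 0.0921.

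Enzymes and transporters of the kidney gave the widest differences outside the sex chromosomes. Higher in males were Cyp2j13 (at least 148-fold), Acsm3, a medium-chain acyl-CoA synthetase (66.6-fold, log2 6.06, SE 0.17), Cyp2d9 (32.8-fold) and the transporter Slc22a30 (16.4-fold). Higher in females were Ugt1a2 (242-fold), Ugt1a5 (148-fold), the amino acid transporter Slc7a12 (22.4-fold) and the glutathione transferase Gsta2 (15.8-fold). Their adjusted p ran from 4.08e-06 to 0.0284, the last being Slc22a30, whose call was lost without any male array or without wildtype female 1 (adjusted p up to 0.0967). In males Ugt1a5 was detected on 1 of 4 arrays, and Ugt1a2 and Slc7a12 on 2 of 4. These 3 folds therefore rest largely on background signal in males, and their size is uncertain. Of the dimmer Acsm3 probes 1 gave 1.02 (adjusted p = 0.0734). The 2 Ugt1a genes and the 2 Cyp2 genes belong to families of closely similar sequence, so which member a probe reads is uncertain. In all, 730 probes passed (314 higher in males, 416 higher in females), for 190 and 275 genes, and 4801 had an unadjusted p under 0.05. Each sample number belongs to 1 sex, and the fit, which treats the arrays as independent, takes no account of any pairing in the sex effect. With the sample number as a random block 522 probes passed. The count was 1120 in the authors' processed values and between 224 (without wildtype female 1) and 772 (without mutant male 2) with single arrays left out; it was 270, 283 and 288 without mutant female 1, mutant female 3 and wildtype female 3, and 290 and 280 without wildtype males 2 and 4. With cyclic loess the calls split into 356 and 356.

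Among the lists, endothelial genes were higher in males than in females: pan-endothelial by a median of 0.60 (18 of 19 above 0, adjusted p = 1.11e-05), capillary and venous by 0.65 (Gpihbp1 1.02, past the threshold over all genes) and arterial by 0.49 (9 over the list alone; Hey1 0.87, past the threshold over all genes). T and NK cell genes (1.04), proliferation genes (0.53, Mcm6 0.95), antigen presentation genes (0.50), macrophage and dendritic cell genes (0.46, with Fcgr3 0.98 and Tyrobp 0.87 past the threshold over all genes) and interferon response genes (0.33, Bst2 1.01) were higher as well. The pan-endothelial excess lay mainly in wildtype males (array means 11.10 and 11.45); mutant male 2 (9.99) was below all 4 female arrays (10.19 to 10.47). Without mutant male 4 its median was 0.33, and without mutant male 2 the T and NK median was 0.55. Without wildtype male 2 the macrophage and dendritic cell median was 0.28. None of the 8 calls held with an estimated correlation (smallest adjusted p = 0.582 with an estimated correlation). The T and NK call was lost without wildtype female 3 (0.97, adjusted p = 0.0673), and the interferon call without mutant female 1 (0.26), wildtype female 1 (0.26), mutant male 4 (0.15) or wildtype male 4 (0.28). Proximal tubule genes went both ways (median -0.11, adjusted p = 0.332): the transporter Slc22a6 (1.23) and Cyp2e1 (1.81) were higher in males, and Gatm (-1.72), Slc5a12 (-1.11) and the glucose transporter Slc5a2 (-0.77) higher in females. On the lower side, Tyms among proliferation genes (-0.52) and Fcer1g among macrophage genes (-3.72) passed over the list alone. Tgfb1, a member of the mesenchymal and TGF-beta lists, was higher in males by 0.79 (adjusted p = 0.0474).

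**Figure D5:**
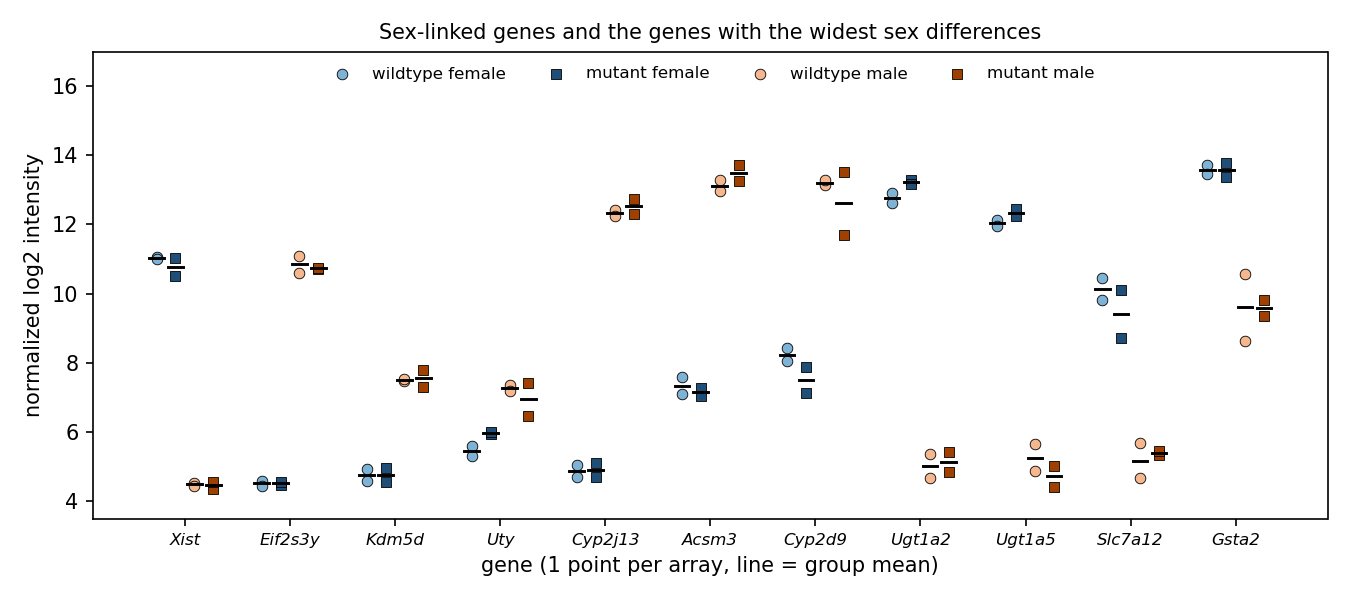
Normalized log2 intensity (vertical axis) of sex-linked genes and of the genes with the widest sex differences; each point is 1 array, colours and shapes mark genotype and sex, and lines are means of 2 arrays. Xist is high on the 4 female arrays (10.52 to 11.06), and the Ugt1a2 difference is -7.92.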

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

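In the male fractions endothelial genes were lower in mutants, with a pan-endothelial median of -0.96 widest within that list for Tie1 (-1.35) and Sox18 (-1.30), and the female median was -0.18. The male call was lost with an estimated correlation (adjusted p = 0.345) and with fry (adjusted p = 0.191). The tests of causes in this part were chosen only after the result was seen. Mutant male 2, whose array had the lowest median signal, carried much of the difference. Without it, with only mutant male 4 left on that side, the median was -0.51 (95% bootstrap interval -0.65 to -0.16). That interval resampled the genes of the list and holds no spread between arrays, so whether that array alone made the shift could not be told. The mean of the list on mutant male 4 (10.90) also lay below both wildtype males (11.10 and 11.45). All 4 mutants lay below the wildtype array of the same number. Mutant male 4 lay above all 4 female arrays (10.19 to 10.47), so the wildtype males stood apart too. A smaller share of endothelial RNA in mutant than in wildtype male fractions could also lower these genes together, with other cells at or above 0. The highest and lowest of the 12 other-cell medians lay 1.89 standard errors apart (lowest erythroid, -1.37, with a wide error). The gap was 3.06 over the 10 lists of at least 6 genes (lowest neutrophil, -1.08) and 1.80 over the 6 of cells without CD31. These errors come from resampling genes, not arrays. The sets of 12 and 6 were chosen after a gap was seen, and as the sets disagree this cause stays open. With 5 other ways of background correction and normalization the median was -0.85 or lower (-0.85 with median scaling, -0.98 in the authors' processed values). Neither the background correction nor the quantile step used here therefore made the shift alone. All 5 bring the arrays to a common level, so an effect that they share is not excluded.

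Of 30 lists, 12 differed between the sexes in their genotype difference with the preset correlation, and none with an estimated one. For pan-endothelial genes the male difference minus the female one had a median of -0.86. For glomerular genes it was -1.07, with a female median of 0.21 and a male one of -0.87. Arterial genes gave -0.40 (-0.16 in females, -0.65 in males). Endothelial activation and adhesion genes gave -0.68 (0.51 and -0.19). Collagens and matrix genes gave -0.31 (0.44 and 0.10). Interferon response genes gave -0.44 (-0.17 and -0.58). Proximal tubule genes gave 0.23 (-0.10 and 0.09). Collecting duct genes gave 0.47 (0.00 and 0.37). Fibroblast genes gave -0.90 (0.78 and 0.12). Macrophage and dendritic cell genes gave -0.52 (0.43 and 0.15). Neutrophil genes gave -0.98 (0.54 and -1.08). Platelet genes gave -0.59 (0.20 and -0.23).

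Single arrays stood apart by Dixon's ratio in 4 of the 180 groups of 4 tested, where chance alone gives about 1 in 20. Aqp2 was higher in wildtype female 3 (12.45) than in the other wildtype arrays (12.06 to 12.10), a ratio of 0.903. Cd22 was higher in wildtype male 2 (6.28, others 4.62 to 4.88), a ratio of 0.841. Xist was lower in mutant female 1 (10.52) than in the other female arrays (up to 11.06), a ratio of 0.873. The median raw signal of wildtype male 2 (98.5) lay above that of the other wildtype arrays (93.9 to 94.2), a ratio of 0.935.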

How the results depend on the processing

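Of the alternatives below, the endothelial score as a covariate, and the lists without background correction, with median scaling and with cyclic loess, were chosen after the result was seen. Called probes of the genotype effect numbered 9. They numbered 0 in the authors' processed values, 1 with no filter, 4 with the strict filter, 3 with genotype only, 0 with the replicate block, 0 with the endothelial score as a covariate and 5 genes with probes averaged per gene, which were Crim1, Aoc1, Serpina10, Ubd and Igfbp2. With the random block they stayed at 9. Leaving out single arrays gave 0 to 1. In males the 1 called probe became 0 in the authors' values, with the strict filter, the replicate block and the covariate, and 0 to 8 without single arrays. The sex effect moved from 730 to 1120 in the authors' values, to 522 with the random block and to between 224 and 772 without single arrays. The cause of these moves was not tested.

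Crim1 stayed lower throughout: -0.72 in the authors' values (adjusted p = 0.147), -2.33 with no filter (adjusted p = 0.0764), with genotype only (adjusted p = 0.183) and with the replicate block (adjusted p = 0.147), -2.36 with the covariate (adjusted p = 0.199), and -2.50 to -2.15 without single arrays. The 13 lists called for the genotype effect became 0 with an estimated correlation and 0 with fry. With the replicate block antigen presentation lost its calls over both sexes and in males, as did Aoc1, Serpina10, Ubd and Igfbp2 (adjusted p from 0.147 to 0.458). Antigen presentation lost the same 2 calls with median scaling (-0.123, adjusted p = 0.109, and -0.196, adjusted p = 0.0794), and interferon response its call between the sexes with cyclic loess (0.353, adjusted p = 0.0554). With no filter neutrophil genes lost theirs in females (0.271, adjusted p = 0.122) and in the interaction (-0.419, adjusted p = 0.0930). With the covariate 6 of the 13 lists kept their call over both sexes, 4 of 10 in males, 9 of 10 in females and 6 of 12 in the interaction.

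A sign changed with the covariate for Mmrn1 (0.27), Il2rb (0.0756), the macrophage and dendritic list over both sexes (-0.0949), and in the interaction the arterial (0.0114), collagens and matrix (0.0813) and interferon response (0.0198) lists. Atp5b changed sign with median scaling (0.0267). Without single arrays Cd79b ran from -0.47 to 0.11, Cd22 from -0.48 to 0.30, Hba-a1 from -1.72 to 0.19, Kdm5c between sexes from -0.26 to 0.31, and mural and mesangial genes in females from -0.48 to 0.0178.

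Over the alternatives, 1075 of 1078 values of uncalled genes, 160 of 183 of called genes and 434 of 567 of lists gave the same answer. Without single arrays it was 694 of 704, 89 of 144 and 375 of 424, so 55 values of called genes lost their call. An uncalled gene gave the same answer if it kept its sign and stayed uncalled, so the high shares of uncalled genes say little about robustness. Females and the interaction had 0 called probes under every alternative applied to them. The chip could not be used as a block because the labels and headers do not name it. The additive design was not applied to the within-sex contrasts or the interaction, genotype only and probes averaged per gene not beyond the genotype effect, and the covariate and the fixed block not to the sex effect. Lists were not run with the strict filter, the additive design, genotype only or the random block.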

Other observations

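Tubule transcripts gave bright signals in the CD31-sorted fractions, with Slc34a1 at percentile 99.8 or higher and Slc12a1 between 99.6 and 99.8 on every array. Endothelial genes spanned a wide range, with Emcn between 98.6 and 99.7, Egfl7 between 98.2 and 99.6 and Cdh5 between 85.0 and 93.7. The tests of the injury pattern were chosen only after the result was seen; those of the neighbours of Crim1 and of the splits were fixed before. Signals of blood cell lists differed between arrays. The erythroid list had a mean of 9.12 in mutant female 3 and 11.31 in mutant female 1. The T and NK list ran from 5.98 in wildtype female 3 to 7.85 in mutant male 2. Whether cell content gave these differences was not tested.

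Injury genes, led by Havcr1 and Lcn2, were higher in mutants by a median of 0.75. That call was lost with an estimated correlation (adjusted p = 0.396) and with fry (adjusted p = 0.121). If more tubule RNA in the mutant fractions were the cause, the tubule lists could be expected to rise as far. The median over the 29 genes of the proximal and the loop and distal tubule was -0.00181. The upper end of its 95% bootstrap interval, which resampled genes and not arrays, was 0.11. This argues against more intact tubule RNA of these segments. It does not exclude it, because the median gene of both lists lay at percentile 98.4 or higher, where signals may rise little. The collecting duct median, 0.19 (upper end of the same kind of interval 0.23), also lay below the injury median, which argues against collecting duct RNA alone. It was 0.37 in males and, without mutant male 2, 0.30 over both sexes. Its call was lost without any of 4 single arrays (0.05 without mutant male 4) and with an estimated correlation (adjusted p = 0.659). The injury shift did not come from 1 or 2 mutant arrays alone. In at least 3 of 4 mutants 9 of the 10 genes were higher than in the wildtype array of the same number, and 7 of them in 4 of 4. Damaged tubule cells in mutant kidneys, or damage during the preparation, may remain as causes, and the arrays do not part them. Lcn2 is also in the neutrophil list and Timp1 in the matrix list, and other cells were not tested as a source of the injury shift.

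Genes that neighbour Crim1 on its chromosome differed between genotypes more often than others: 16 of 98 (16.3%) against 1022 of 12352 (8.27%) had an unadjusted p under 0.05 (one-sided Fisher's exact p = 0.00685). Of the 16, 12 were lower in mutants, among them Xdh (-1.38), Ehd3 (-1.15), Ltbp1 (-1.05), Myl12a (-0.73) and Qpct (-0.55). Across these genes, which are not independent replicates, the female and male differences had an r of 0.57, against -0.01 over the others, a comparison chosen after the result was seen. On a mixed background, alleles carried along with the insertion could give this pattern, so the values of Ehd3 and Ltbp1, members of the glomerular and TGF-beta lists, may reflect strain rather than loss of Crim1. Both genes differed more in males than over both sexes, as the pan-endothelial list did (-0.96 in males, -0.18 in females), so that shift may contribute too. The test treats genes that vary together as independent, and it does not exclude an effect of Crim1 on its neighbours.

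Chance cannot be excluded for the number of probes called between genotypes, nor for the excess of small unadjusted p (1853, highest other split 2076, and 1811 among splits balanced for sex). With sex as an additive term, 2 of the 34 splits of the arrays into 4 and 4 that can be fitted beside sex gave as many calls as the real split (6). The highest other count, 13, came from a split with 3 arrays of 1 sex on a side. The split by sex itself cannot be fitted beside sex and is left out, as is the split by genotype in the count for the sex effect, a choice made after the counts were seen. If the numbers pair the samples, the real split is best compared with the 8 that part all 4 pairs. The other splits keep at least 1 pair together. Of these 8 only the real one reached its count (highest other 0), but a share of 1 in 8 is too large to exclude chance. For called lists chance cannot be excluded either: 2 of 34 splits reached the real count of 12 (highest other 12, median of the others 8), and 2 of the 8 that part all pairs. For the sex effect chance can be excluded if the samples are unpaired: 1 of 34 splits, the real one, reached 729 (highest other 19). If the numbers pair the samples, only the 3 splits that part no pair compare with it. Of these the real one alone reached its count (highest other 1), but a share of 1 in 3 is too large to exclude chance.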
